A study of Homo sapiens with 38 samples.

How the data were processed

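The data are Affymetrix arrays of IMR90 human fibroblasts, hybridised with biotin-labelled cRNA made from 1 µg of total RNA. Per the labels, cells carried the empty MLP vector or a hairpin against RB, p107 or p130, and were growing in medium with 10% serum, kept in 0.1% serum, confluent, or senescent after ras expression. The 38 arrays form 19 groups of 2. In experiment 1, 32 arrays cover the 4 states with vector, shRB, shp107 and shp130. In experiment 2, 6 arrays cover growing vector, senescent vector and senescent shRB cells. Every array column was used. The labels do not state that replicates are separate cultures, so p-values measure only the spread between arrays, pooled over the groups of an experiment, which may be technical.

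The deposited values are on a log2 scale, 1 value per probe set and array. They were made with GCRMA per the submitters' processing notes. Whether all 38 arrays were processed together is not given in the sources used here. The values were used as deposited. Values ran from 0.86 to 13.88. Group means under the array median, such as CDKN2B and TNFSF15 in growing cells, are at background, so such changes are lower bounds. Control probe sets were not used here, so a check of RNA quality from the 3' and 5' ends of control transcripts was not made.

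Of 54613 probe sets, 41091 named 1 gene, 1801 named several and 11721 were not matched to a gene here. Each of 19775 genes was represented by the probe set with the highest mean over the 38 arrays among those that named it alone. Genes with a log2 value above 5 on at least 2 of the arrays of experiment 1 were tested, which left 8511.

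Each experiment was fitted apart with limma 3.58.1 in R 4.3.3, with 1 mean per group, contrasts between groups and moderated variances from eBayes. The residual degrees of freedom were 16 and 3 in experiments 1 and 2, and the prior degrees of freedom 4.85 and 5.35. P-values were adjusted within each contrast by the Benjamini-Hochberg method over the 8511 genes, and a gene was called at an adjusted p under 0.05. A second count took called genes that changed at least 2-fold. Errors after ± are standard errors (SE) of a log2 change, or standard deviations (SD) where a group mean is given. Every comparison of 2 groups has n = 2 against n = 2, and differences of the shRB effect use 4 groups of 2. Experiment 1 had 20 contrasts, namely 3 between states in vector cells, 3 hairpins against vector in each of 4 states, 3 differences of the shRB effect between states and 2 between hairpins in senescent cells. Experiment 2 had 2. Tables were read with data.table (version 1.17.8), and genes and figures were prepared in Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.

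The 17 gene lists were written before the data were examined, as were the comparisons, the thresholds, the genes to be named and most of the alternatives. A list was tested where at least 2 members passed the filter. The tested lists, with genes tested, were DNA replication (42), mitosis (45), pocket proteins and E2F family (9), cell cycle inhibitors (5), p53 targets (20), secreted inflammatory factors (19), secreted proteases and growth factor regulators (26), RAS and ERK response (19), fibrillar collagen and matrix (29), contractile and myofibroblast (18), cholesterol synthesis (17), interferon response (10), lysosome (23), serum immediate early response (16) and endothelial markers (2). No epithelial or blood marker passed the filter, with highest log2 values of 4.27 and 3.92. The highest endothelial marker value was 9.52. List members that matched no probe set used here were not analysed here. Lists were tested with fry, which asks whether the genes of a set move, on balance, one way and does not compare them with other genes. The scale fry gives a gene depends on the axes chosen for the residuals, and by default these change with rounding. After the results were seen they were therefore fixed as the differences within groups, taken in array order. With the default axes, the immediate early list in low serum had passed. The p-values of fry were adjusted over 300 tests of list and contrast in experiment 1 and 30 in experiment 2. As an alternative, camera compared each list with the other genes, with the correlation between genes estimated from the residuals. The text gives the list median of the log2 changes, the members called over all genes, and the number called when p-values were adjusted over the list alone.

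The named-gene rule was as follows. RB1, RBL1 and RBL2 come first with all their probe sets. Each state comparison and each shRB comparison then gives the 10 largest rises and 10 largest falls among called genes whose 2 groups do not overlap. The other comparisons give the first 5 each way. A list that passed fry adds up to 4 called members with the largest changes. Cell cycle inhibitors and pocket protein and E2F genes are all taken in the senescent comparisons. Unnamed or provisional symbols were left out. From this set, the text gives mainly genes whose call held with each array left out in turn, and names the array where it did not.

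Each array of the compared groups was left out in turn, with limma pooling the spread, so that the lone array left in a group is assumed to vary like the other groups. Other alternatives were no filter on dim genes, the mean of a gene's probe sets, probe sets ending in x_at or s_at left out, only the arrays of the groups compared, all 38 arrays in one fit, the replicate number as a block over all states or within each state, a variance prior with a trend and robust weights, quantile normalization and a shift of each array to one median. Chosen after seeing the data were 4 alternatives, namely the confluent shp130 arrays as the reference for confluent shRB and for confluent shp107, a crossed replicate block, and the E2F family list without RB1, RBL1 and RBL2. Replicate differences of the compared groups were correlated to see whether the replicate numbers paired the arrays, which share only a number.

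Hairpin effects in the same state share the vector arrays. The correlation this gives by chance was found from 20 simulations with no true change, and a correlation was also computed from contrasts that share no array. Genes that fell in senescence in experiment 1 were followed in the shRB effect of experiment 2, and the reverse, so that no array entered both sides.

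The fits were tested on simulated data made from the gene means and residual SDs of these arrays, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. In the senescent vector comparison 4.48%, 46.3% and 89.4% of these were recovered, in the senescent shRB comparison 8.96%, 43.3% and 90.9%, and in the difference of the shRB effect between senescent and growing cells 2.99%, 16.4% and 69.7%. In experiment 2 the 4-fold shares were 81.8% for senescence and 86.4% for shRB. Between 3 and 8 unchanged genes were called per comparison. A list shifted by 0.5 had adjusted fry p-values of 4.02e-05, 1.4e-05 and 1.045e-05 in experiment 1 and 0.143 and 0.0273 in experiment 2, and 0 of 40 unshifted lists passed. The simulated genes were independent, so this does not give the error rate of fry for correlated lists.

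Quantile normalization moved the median change of all genes by 0.12 in the senescent comparison and by -0.12 in the difference of the shRB effect between senescent and confluent cells. Other medians moved by less than 0.1.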

Results

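Gene expression was measured with microarrays in IMR90 human fibroblasts that carried an empty vector or a short hairpin RNA against RB (shRB), p107 (shp107) or p130 (shp130). Cells were growing, kept in low serum, confluent, or senescent after expression of ras. Experiment 1 held 32 arrays, with 2 for each of the 16 pairings of hairpin and state. Experiment 2 held 6 arrays of growing vector, senescent vector and senescent shRB cells, again n = 2 per group. The median log2 value of an array lay between 3.27 and 3.41, 21.6% to 24.2% of probe sets had a log2 value above 5, and the number of arrays limits the precision. Replicates correlated over all probe sets with r from 0.9795 to 0.9969.

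The hairpin targets were examined first, in every group. The gene RB1, which encodes RB, had a log2 value of 9.44 ± 0.07 (mean ± SD, n = 2) in growing vector cells and 5.39 ± 0.28 in growing shRB cells. It was 9.83 ± 0.03 against 5.59 ± 1.22 in low serum, 9.76 ± 0.07 against 4.66 ± 0.16 at confluence and 9.39 ± 0.34 against 4.06 ± 0.60 in senescent cells. The change of RB1 with shRB in these states was -4.05, -4.24, -5.10 and -5.32 (SE 0.36), with adjusted p of 1.8e-06, 7.86e-07, 1.83e-09 and 1.95e-09. In experiment 2 senescent cells RB1 went from 9.14 ± 0.10 to 6.86 ± 0.31, a change of -2.28 ± 0.21 (adjusted p = 0.000457). The change of RB1 with shp107 or shp130 lay between -0.32 and 0.49 and was not called in any state, and a second, dim RB1 probe set was called in no comparison.

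RBL2, which encodes p130, fell with shp130 from 7.69 ± 0.03 to 5.34 ± 0.21 in growing cells, from 8.24 ± 0.33 to 5.59 ± 0.38 in low serum, from 8.31 ± 0.03 to 5.46 ± 0.13 at confluence and from 7.58 ± 0.14 to 4.69 ± 0.08 in senescent cells (mean ± SD, n = 2 per group). These changes were -2.35, -2.65, -2.85 and -2.88 (SE 0.26), with adjusted p of 6.78e-05, 1.78e-05, 4.79e-06 and 9.79e-07. With shRB or shp107 RBL2 changed by -0.67 to 0.32 in experiment 1 and was not called. RBL1, which encodes p107, was dim, with log2 values of 4.31 ± 0.10 in growing and 3.34 ± 0.14 in senescent vector cells. With shp107 its change was -0.74, -1.30, -0.48 and -0.13 (SE 0.54) in growing, low-serum, confluent and senescent cells and was not called in any of these states, nor were 3 further RBL1 probe sets. A second RBL2 probe set was not called with shp130 in any state (-0.21, -0.53, -0.60 and -0.13). In experiment 2 RBL1 fell with senescence from 5.02 ± 0.25 to 2.53 ± 0.004 (adjusted p = 7.0e-05), and rose with shRB to 4.60 ± 0.44, a change of 2.07 ± 0.23 (adjusted p = 0.00108).

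**Figure D1:**
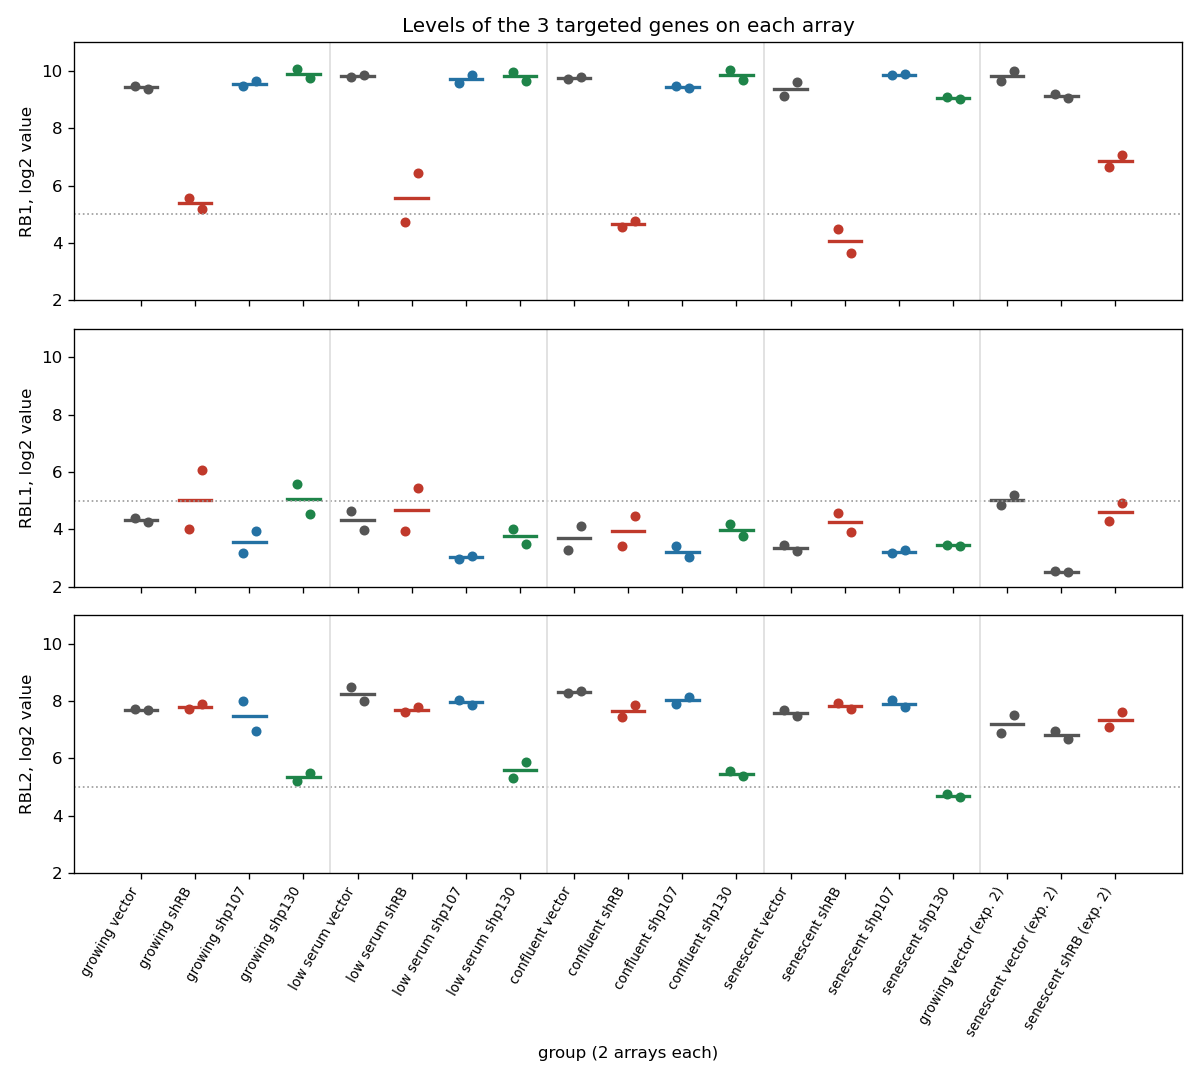
Log2 values (vertical axis) of RB1, RBL1 and RBL2 in each group (horizontal axis). Points are arrays, short lines are means of 2 arrays and the dotted line marks the log2 value of 5, which RBL1 rarely passed.

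Vector cells in low serum were compared with growing vector cells to see which genes changed on serum withdrawal. At an adjusted p under 0.05, 1110 of 8511 genes changed, 569 higher and 541 lower, and 783 of them at least 2-fold. The platelet-derived growth factor gene PDGFD rose by 5.47 ± 0.63 (log2 change ± SE, n = 2 per group, adjusted p = 6.6e-06), from 3.92 ± 0.20 to 9.39 ± 0.79. The adhesion molecule gene VCAM1 rose by 5.33 ± 0.68 (adjusted p = 2.2e-05) and CDKN2B, which encodes the CDK inhibitor p15, by 5.23 ± 0.70 (adjusted p = 3.74e-05), from 2.83 ± 0.13 to 8.06 ± 0.37. The glycoprotein hormone gene STC1 fell by 6.07 ± 0.39 (adjusted p = 2.15e-09), from 10.82 ± 0.60 to 4.75 ± 0.28. The nuclear receptor NR4A2 fell by 4.12 ± 0.41 (adjusted p = 1.26e-06). The count of 1110 was 579 without growing vector replicate 1, 439 without growing vector replicate 2 and 460 without low-serum vector replicate 1.

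Of 45 mitosis genes, 35 fell in low serum, 0 rose and 10 were not called, with a median change of -1.94 and 43 lower when adjusted over the list alone (fry adjusted p = 7.65e-05, adjusted p = 0.0806 with an estimated correlation). The securin gene PTTG1 fell by 3.83 ± 0.47. Of 42 DNA replication genes, 14 fell, 0 rose and 28 were not called, with a median of -0.80 and 20 lower when adjusted over the list alone (fry adjusted p = 0.00288, adjusted p = 0.221 with an estimated correlation). Among them thymidine kinase TK1 fell by 3.09 ± 0.39. Of 17 cholesterol synthesis genes, 14 rose and 0 fell, with a median of 1.99 and 15 higher when adjusted over the list alone (fry adjusted p = 2.38e-06, camera adjusted p = 0.0493). The synthase HMGCS1 rose by 3.85 ± 0.42 (adjusted p = 4.19e-06) and the sterol sensor INSIG1 by 3.77 ± 0.42. Of 29 matrix genes, 8 rose and 0 fell, with 13 higher when adjusted over the list alone and a median of 0.74, which was 0.49 without growing vector replicate 2 (fry adjusted p = 0.00216, adjusted p = 0.27 with an estimated correlation).

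Of 26 secreted protease and growth factor regulator genes, 8 fell in low serum and 1 rose, with a median of -0.27 and 9 lower and 1 higher when adjusted over the list alone (fry adjusted p = 0.000214, adjusted p = 0.158 with an estimated correlation). Of 5 cell cycle inhibitors, 2 rose, with a median of 0.41 (fry adjusted p = 0.000989, adjusted p = 0.221 with an estimated correlation). They were CDKN2B and CDKN1B, the p27 gene, whose rise of 1.47 lost its call without growing vector replicates 1 and 2 (adjusted p = 0.141 and 0.0988) and low-serum vector replicates 1 and 2 (adjusted p = 0.162 and 0.0745). The call of the p53 target list, with a median of 0.29, 3 genes higher and fry adjusted p = 0.0314, was lost with an estimated correlation (adjusted p = 0.537 with an estimated correlation). It was also lost with any 1 array left out. The immediate early list (-0.11, fry adjusted p = 0.0518) and the inflammatory list (-0.79, fry adjusted p = 0.284) did not pass. The E2F family (0.34), RAS and ERK (-0.03), lysosome (0.15) and endothelial (0.28) lists did not pass.

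Confluent vector cells were compared with growing vector cells for the response to cell density. Here 2134 genes changed, 896 higher and 1238 lower, and 1381 at least 2-fold. The count was 909 without growing vector replicate 2. The chemokine genes CXCL3 and CXCL5 rose by 8.13 ± 0.38 (adjusted p = 2.92e-12) and 7.85 ± 0.29 (adjusted p = 6.48e-14), CXCL5 from 3.67 ± 0.24 to 11.52 ± 0.88 (mean ± SD, n = 2). The EGF-family ligand EREG rose by 6.01 ± 0.24 (adjusted p = 2.63e-13). The flippase ATP8B1 fell by 5.04 ± 0.53 (adjusted p = 9.09e-07) and the receptor ligand GAS6 by 4.45 ± 0.39 (adjusted p = 6.96e-08).

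Of 45 mitosis genes, 41 fell at confluence and 0 rose, with a median of -2.71 and 44 lower when adjusted over the list alone (fry adjusted p = 1.11e-05, adjusted p = 0.135 with an estimated correlation), among them cyclin B1, CCNB1, by 3.96 ± 0.60. The DNA replication list had 23 of 42 genes lower and 0 higher, with a median of -0.99 and 28 lower when adjusted over the list alone (fry adjusted p = 0.000306, adjusted p = 0.259 with an estimated correlation). The methylation factor UHRF1 fell by 3.82 ± 0.48 and TK1 by 3.38 ± 0.39. Of 18 contractile genes, 12 fell and 0 rose, with a median of -0.95 and 14 lower when adjusted over the list alone (fry adjusted p = 4.37e-07, adjusted p = 0.0647 with an estimated correlation). Calponin CNN1 fell by 3.27 ± 0.30 (adjusted p = 1.21e-07) and smooth muscle actin ACTG2 by 2.93 ± 0.35. In the protease list 10 genes rose and 1 fell, also when adjusted over the list alone. Its median was 0.47, or 0.21 without growing vector replicate 2 (fry adjusted p = 3.00e-06, adjusted p = 0.0787 with an estimated correlation). The binding protein IGFBP2 rose by 4.77 ± 0.63 and stromelysin MMP3 by 4.53 ± 0.64.

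Of 19 secreted inflammatory genes, 15 rose at confluence and 0 fell, with a median of 2.98 and 16 higher when adjusted over the list alone (fry adjusted p = 1.97e-05, adjusted p = 0.173 with an estimated correlation). The 2 confluent vector arrays stood apart from each other more than any other replicates, with an SD of 0.794 for their difference over the genes tested, and their means over the inflammatory genes were 11.7 and 8.93. The list median was 1.34 without confluent vector replicate 1 and 6.02 without confluent vector replicate 2. Of 16 immediate early genes, 6 rose and 1 fell, with a median of 0.54 (fry adjusted p = 6.10e-05, adjusted p = 0.158 with an estimated correlation), which was 0.24 without confluent vector replicate 1 and 0.81 without confluent vector replicate 2. NR4A2 rose by 3.59 ± 0.41 and the transcription factor gene FOS by 2.79 ± 0.34. The matrix list had a median of -0.06 and a mean of 0.24, with 5 genes higher and 5 lower, and did not pass. The E2F family (0.32), p53 target (0.14), cholesterol (-0.14), interferon (0.20), endothelial (0.41), cell cycle inhibitor (0.34), RAS and ERK (0.35) and lysosome (-0.20) lists did not pass. The inhibitor median was 0.41 without confluent vector replicate 1, and the RAS and ERK and lysosome medians 0.74 and -0.45 without confluent vector replicate 2.

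Senescent vector cells were compared with growing vector cells to describe the ras-induced state. In experiment 1, 2166 genes changed, 784 higher and 1382 lower, and 1477 at least 2-fold. The split was 1104 higher and 1136 lower after quantile normalization, which made 49.3% higher in place of 36.2%. The count was 1337 without growing vector replicate 2 and 1420 without senescent vector replicate 1. The TNF-family gene TNFSF15 rose by 8.64 ± 0.61 (adjusted p = 1.3e-09), from 3.21 ± 0.15 to 11.85 ± 0.06. CXCL5 rose by 8.48 ± 0.29 (adjusted p = 1.34e-14), from 3.67 ± 0.24 to 12.15 ± 0.01, CXCL3 by 7.80 ± 0.38 and CDKN2B by 7.96 ± 0.70 (adjusted p = 3.32e-08), from 2.83 ± 0.13 to 10.79 ± 0.42. The cytokine IL1A rose by 7.14 ± 0.97 (adjusted p = 1.11e-05). Collagen COL15A1 fell by 6.52 ± 0.53 (adjusted p = 1.19e-08), from 10.21 ± 1.67 to 3.68 ± 0.01.

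Of 45 mitosis genes, 40 fell in senescent cells and 0 rose, also when adjusted over the list alone, with a median of -2.89 (fry adjusted p = 7.81e-06, adjusted p = 0.153 with an estimated correlation). Among 42 DNA replication genes, 26 fell and 0 rose, with a median of -1.20 and 31 lower when adjusted over the list alone (fry adjusted p = 8.96e-06, adjusted p = 0.158 with an estimated correlation). Thymidylate synthase TYMS fell by 3.93 ± 0.32 (adjusted p = 1.37e-08), TK1 by 3.55 ± 0.39, UHRF1 by 3.53 ± 0.48 and the licensing inhibitor GMNN by 3.09 ± 0.41. Of 5 cell cycle inhibitors, 3 rose and 1 fell, with a median of 1.13 (fry adjusted p = 5.91e-05, adjusted p = 0.221 with an estimated correlation). Beside CDKN2B, the p21 gene CDKN1A rose by 1.58 ± 0.24 (adjusted p = 3.71e-05) and CDKN2A, which encodes p16 and ARF, by 1.13 ± 0.23 (adjusted p = 0.00083), and the p57 gene CDKN1C was not called (-0.26). The p27 gene CDKN1B fell by 1.58 ± 0.43 (adjusted p = 0.00932), lost without growing vector replicate 2 and senescent vector replicate 2 (adjusted p = 0.0735 and 0.0706). The list of pocket proteins and the E2F family did not pass, with a median of -0.12 and a mean of 0.21. In it E2F7, a repressor, rose by 4.37 ± 0.35 (adjusted p = 7.53e-09), while RB1 (-0.05), RBL1 (-0.97), RBL2 (-0.12), E2F3 (-0.10), E2F5 (-0.14), E2F6 (0.48) and TFDP1 (-0.46) were not called. TFDP2 fell by 1.16 ± 0.40 (adjusted p = 0.0355), lost without growing vector replicates 1 and 2 (adjusted p = 0.0766 and 0.189) and senescent vector replicates 1 and 2 (adjusted p = 0.0887 and 0.163).

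Of 19 secreted inflammatory genes, 11 rose in senescent cells and 1 fell, with a median of 2.55 and 12 higher and 1 lower when adjusted over the list alone (fry adjusted p = 0.000338, adjusted p = 0.267 with an estimated correlation). The median was 3.84 without growing vector replicate 1 and 1.26 without growing vector replicate 2. Beside CXCL5 and IL1A, the chemokine CCL20 rose by 6.43 ± 1.01 (adjusted p = 6.21e-05). In the protease list 9 genes rose and 5 fell. Its median was 0.32 (fry adjusted p = 2.71e-06, adjusted p = 0.153 with an estimated correlation). It was 0.18 without growing vector replicate 2 and 0.13 without senescent vector replicate 2. EREG rose by 6.57 ± 0.24, MMP3 by 5.19 ± 0.64 and the proteoglycan gene ESM1 by 4.53 ± 0.24. Of 19 RAS and ERK response genes, 12 rose and 0 fell, with a median of 0.98 and 13 higher and 1 lower when adjusted over the list alone (fry adjusted p = 5.91e-05, adjusted p = 0.153 with an estimated correlation). The phosphatase gene DUSP4 rose by 3.86 ± 0.37.

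Of 18 contractile genes, 12 fell in senescent cells and 0 rose, with a median of -0.99 and 15 lower when adjusted over the list alone (fry adjusted p = 4.37e-07, adjusted p = 0.0806 with an estimated correlation). CNN1 fell by 4.33 ± 0.30 (adjusted p = 8.39e-10) and ACTG2 by 2.23 ± 0.35. Of 29 matrix genes, 12 fell and 1 rose, with a median of -0.39 (fry adjusted p = 0.00159, adjusted p = 0.669 with an estimated correlation). Of 20 p53 targets, 5 rose and 1 fell, with a median of 0.09 (fry adjusted p = 0.0223, adjusted p = 0.401 with an estimated correlation). That call was lost without growing vector replicates 1 and 2 (0.05 and 0.25, adjusted p = 0.118 and 0.0557) and senescent vector replicate 2 (-0.01, adjusted p = 0.285), and the median was 0.23 without senescent vector replicate 1. Of 16 immediate early genes, 6 rose and 2 fell, with a median of 0.26 (fry adjusted p = 0.0153, adjusted p = 0.501 with an estimated correlation). This call was lost without growing vector replicate 2 (0.09, adjusted p = 0.0914) and without senescent vector replicate 2 (0.24, adjusted p = 0.1), and the median was 0.48 without growing vector replicate 1 and 0.39 without senescent vector replicate 1. The cholesterol list had a median of 0.53 with 8 genes higher, the lysosome list 0.22 with 7 higher and 3 lower and the interferon list -0.83 with 2 lower, and these did not pass.

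**Figure D2:**
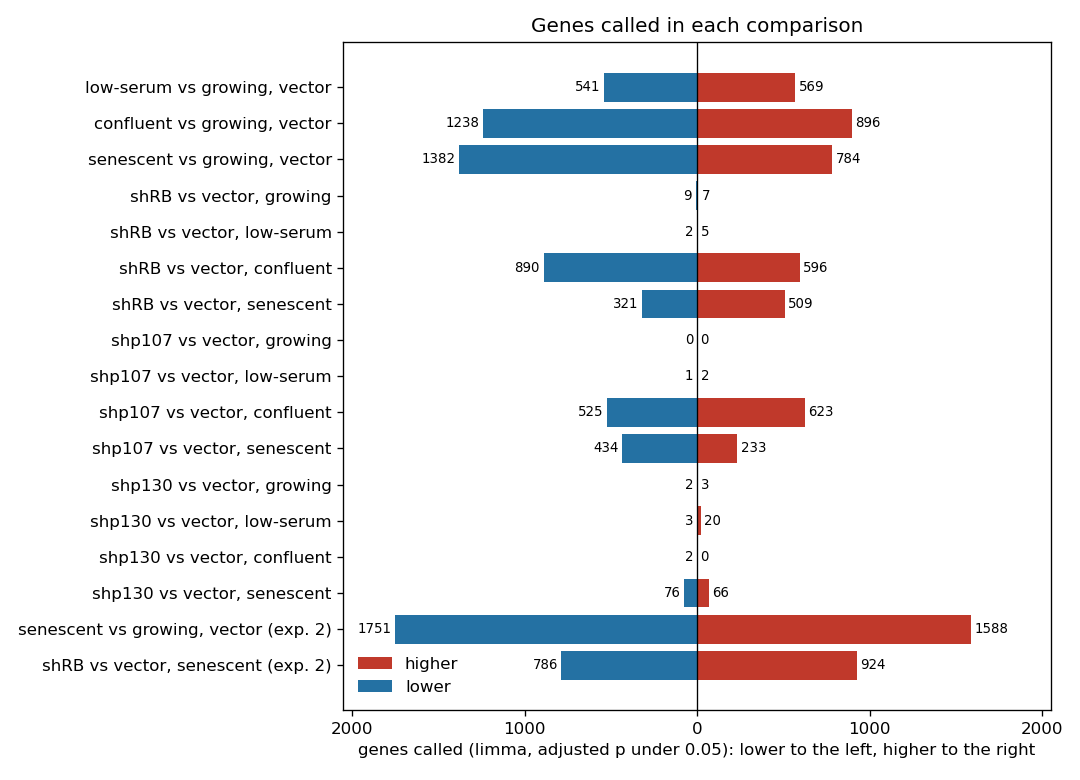
Number of genes called higher and lower (horizontal bars to either side) in each comparison at an adjusted p under 0.05, n = 2 arrays per group. With shRB the bars were short in growing and low-serum cells and long in confluent and senescent cells.

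Each hairpin was next compared with vector in the same state. In growing cells 16 genes changed with shRB, 7 higher and 9 lower, with 537 at an unadjusted p under 0.05. Beside RB1, cyclin E2, CCNE2, rose by 2.15 ± 0.42 (adjusted p = 0.0347), the replication kinase CDC7 by 1.15 ± 0.24 (adjusted p = 0.0476), and the chemokine CXCL8 and NR4A2 fell by 3.87 ± 0.66 (adjusted p = 0.0151) and 2.74 ± 0.41 (adjusted p = 0.00562). These 4 calls were lost without growing vector replicate 1 (adjusted p = 0.255, 0.364, 0.345 and 0.168, with CXCL8 at -2.58), growing shRB replicate 1 (adjusted p = 0.0521, 0.453, 0.0925 and 0.0521) and growing shRB replicate 2 (adjusted p = 0.557, 0.1, 0.16 and 0.0742). Those of CCNE2 and CDC7 were also lost without growing vector replicate 2 (adjusted p = 0.14 and 0.114). The count was 4 and 29 without growing vector replicates 1 and 2, and 1, that of RB1, without growing shRB replicate 1 or 2. Of 42 DNA replication genes, 2 rose and 0 fell, with a median of 0.68 and 16 higher when adjusted over the list alone (fry adjusted p = 0.00628, adjusted p = 0.0608 with an estimated correlation). The mitosis list had a median of 0.78, with 1 gene higher and 10 when adjusted over the list alone, and did not pass (fry adjusted p = 0.0688). The protease list had a median of -0.23, with 1 gene lower and 4 when adjusted over the list alone (fry adjusted p = 0.00726, camera adjusted p = 0.0443), but lost its call without growing vector replicate 1 (adjusted p = 0.153), and its median was -0.40 without growing vector replicate 2.

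In low serum 7 genes changed with shRB, 5 higher and 2 lower, with 704 at an unadjusted p under 0.05, and 8 higher and 1 lower after quantile normalization. The helicase gene MCM6 rose by 1.62 ± 0.26 (adjusted p = 0.0122) and lost its call without low-serum vector replicates 1 and 2 (adjusted p = 0.0793 and 0.0787) and low-serum shRB replicate 2 (adjusted p = 0.0556). The count was 2 without low-serum vector replicate 2 and 16 and 14 without low-serum shRB replicates 1 and 2. The DNA replication list had a median of 0.67, with 2 genes higher and 18 when adjusted over the list alone (fry adjusted p = 0.0086, adjusted p = 0.0647 with an estimated correlation). Its call was lost without low-serum vector replicate 1 (0.44, adjusted p = 0.112) and without low-serum shRB replicate 2 (0.33, adjusted p = 0.179), and the median was 1.02 without low-serum shRB replicate 1. The mitosis list had a median of 0.45 and did not pass (fry adjusted p = 0.411), but passed without low-serum shRB replicate 1 (0.91, adjusted p = 0.0312).

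In confluent cells 1486 genes changed with shRB, 596 higher and 890 lower, against 838 higher and 767 lower after quantile normalization. The count was 851 without confluent vector replicate 1 and 751 without confluent shRB replicate 1. The urea transporter SLC14A1 rose by 5.31 ± 0.52 (n = 2 per group, adjusted p = 4.17e-07), the TNF-family gene TNFSF4 by 5.24 ± 0.31 (adjusted p = 9.98e-11) and ATP8B1 by 4.44 ± 0.53. IL13RA2, a decoy receptor of interleukin 13, fell by 9.29 ± 0.54 (adjusted p = 9.86e-11) and MMP3 by 8.22 ± 0.64 (adjusted p = 9.84e-09). The G protein regulator RGS5 fell by 7.95 ± 0.39, CXCL5 by 7.29 ± 0.29 (adjusted p = 9.58e-14), CXCL3 by 7.20 ± 0.38, EREG by 7.02 ± 0.24 and NR4A2 by 6.75 ± 0.41. With only the confluent vector and shRB arrays, limma called 75 genes.

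Of 19 secreted inflammatory genes, 15 fell with shRB at confluence and 0 rose, with a median of -3.57 and 16 lower when adjusted over the list alone (fry adjusted p = 9.15e-06, adjusted p = 0.153 with an estimated correlation). The array means over these genes were 11.7 and 8.93 with vector, 6.69 and 6.37 with shRB, 6.53 and 6.26 with shp107 and 10.93 and 10.97 with shp130, and the list median was -1.77 without confluent vector replicate 1 and -6.42 without confluent vector replicate 2. In the protease list 12 genes fell and 1 rose, with 13 lower when adjusted over the list alone. Its median was -0.98 (fry adjusted p = 3.16e-08, camera adjusted p = 0.0443). Of 18 contractile genes, 13 rose and 0 fell, with a median of 0.81 and 14 higher when adjusted over the list alone (fry adjusted p = 1.36e-06, camera adjusted p = 0.0493). Of 16 immediate early genes, 6 fell and 0 rose, with 8 lower when adjusted over the list alone (fry adjusted p = 5.35e-06, adjusted p = 0.138 with an estimated correlation), among them FOS by 3.21 ± 0.34. Their median was -0.69, and -0.34 without confluent vector replicate 1. Of 29 matrix genes, 14 rose and 2 fell, with a median of 0.81, which was 0.36 without confluent vector replicate 1 (fry adjusted p = 0.000409, adjusted p = 0.158 with an estimated correlation).

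Of 42 DNA replication genes, 9 rose with shRB at confluence and 0 fell, with a median of 0.42 and 12 higher when adjusted over the list alone (fry adjusted p = 0.0416, adjusted p = 0.471 with an estimated correlation). The list's call was lost without confluent vector replicate 1 (0.54), confluent vector replicate 2 (0.44) and confluent shRB replicate 2 (0.20), and its median was 0.70 without confluent shRB replicate 1. The E2F family list (-0.67, fry adjusted p = 0.00962, adjusted p = 0.758 with an estimated correlation) holds RB1, the target of the hairpin, and without RB1, RBL1 and RBL2 it was not called (-0.56, adjusted p = 0.722). The call was also lost without confluent vector replicate 1 (-0.31) and confluent shRB replicate 1 (-0.45). The mitosis list had a median of 0.29 with 1 gene higher and did not pass (fry adjusted p = 0.472).

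**Figure D3:**
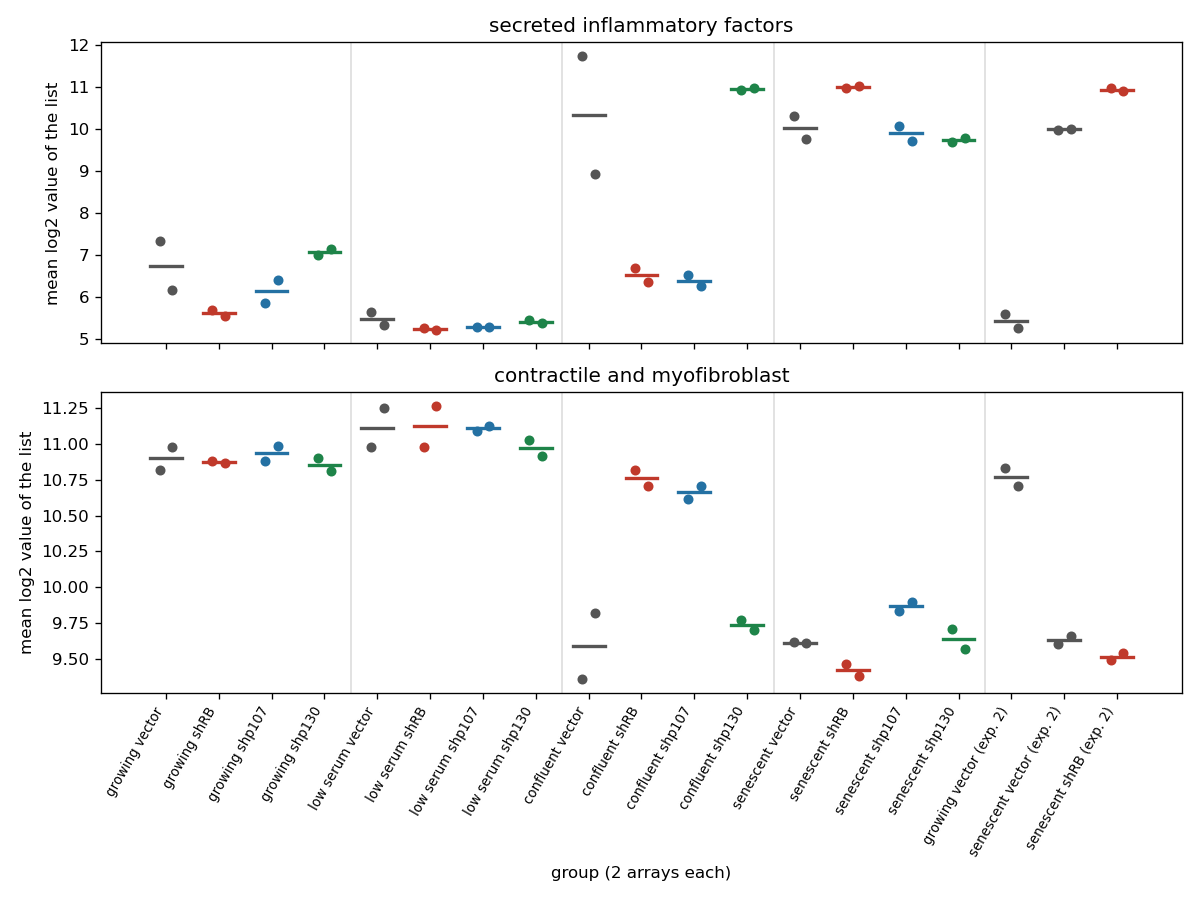
Mean log2 value of the secreted inflammatory list and of the contractile list (vertical axes) on each array of experiment 1, by state and hairpin (horizontal axis). In confluent cells the shRB and shp107 arrays lay below the vector and shp130 arrays for the inflammatory list and above them for the contractile list.

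In senescent cells of experiment 1, 830 genes changed with shRB, 509 higher and 321 lower, and 594 at least 2-fold. The count was 376 without senescent vector replicate 2 and 507 without senescent shRB replicate 1. CCNE2 rose by 5.10 ± 0.42 (n = 2 per group, adjusted p = 3.54e-08), from 3.96 ± 0.13 to 9.06 ± 0.70, and TYMS by 4.31 ± 0.32 (adjusted p = 1.02e-08), from 7.05 ± 0.47 to 11.36 ± 0.16. The protease inhibitor SERPINB4 rose by 5.04 ± 0.48 (adjusted p = 3.08e-07), the chemokine PPBP by 4.79 ± 0.41 (adjusted p = 5.24e-08) and the cytokine IL33 by 4.79 ± 0.73. Beside RB1, the actin-binding NEXN fell by 2.88 ± 0.21 (adjusted p = 5.3e-09).

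Of 42 DNA replication genes, 26 rose with shRB in senescent cells, 0 fell and 16 were not called, with a median of 1.48 and 30 higher when adjusted over the list alone (fry adjusted p = 1.57e-06, camera adjusted p = 0.0443). The clamp loader gene RFC4 rose by 4.06 ± 0.39 (adjusted p = 4.12e-07) and MCM6 by 3.88 ± 0.26 (adjusted p = 1.95e-09). Of 45 mitosis genes, 1 rose, 1 fell and 43 were not called, also when adjusted over the list alone, with a median of -0.12 (fry adjusted p = 0.824). Of 29 matched interferon response genes, 10 passed the filter. Its 2 arrays could be the senescent shRB pair alone, which would favour a rise here. Of these 10 genes, 6 rose and 0 fell, with a median of 1.73 and 7 higher when adjusted over the list alone (fry adjusted p = 4.36e-05, camera adjusted p = 0.0493). The exonuclease gene ISG20 rose by 2.00 ± 0.29 (adjusted p = 7.32e-05) and the interferon-induced IFI6 by 5.07 ± 0.80 (adjusted p = 0.000212), or 3.17 without senescent shRB replicate 1. The means of the shRB arrays over this list were 7.297 and 6.499, against 5.14 and 5.07 with vector. Of 2 endothelial markers tested, 1 rose, the tight junction gene CLDN5 by 3.17 ± 0.27 (list median 1.59, fry adjusted p = 4.77e-05, adjusted p = 0.161 with an estimated correlation). Of 26 genes of the protease list, 4 rose and 1 fell, with a median of 0.25 (fry adjusted p = 0.0069, adjusted p = 0.343 with an estimated correlation). This call was lost without senescent shRB replicate 1, where the median was 0.21. ESM1 rose by 3.60 ± 0.24 (adjusted p = 1.95e-09) and the angiopoietin ANGPT1 fell by 2.00 ± 0.39.

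The cell cycle inhibitors CDKN1A (-0.16), CDKN2A (0.45), CDKN2B (-0.51), CDKN1B (-0.73) and CDKN1C (0.10) were not called with shRB in senescent cells, and neither were E2F3 (-0.46), E2F7 (0.12), TFDP1 (0.70), RBL1 (0.90) and RBL2 (0.25). CDKN1B was called without senescent shRB replicate 1 (-1.74, adjusted p = 0.0067). The inflammatory list had a median of 0.83 with 2 genes higher (fry adjusted p = 0.364) and the lysosome list -0.33 with 1 higher and 4 lower (fry adjusted p = 0.122), and neither passed. The immediate early list had a median of 0.03 and a mean of -0.11. The p53 target (-0.14), RAS and ERK (-0.29), matrix (0.08), contractile (-0.26) and cholesterol (-0.07) lists did not pass either.

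With shp107, 0 genes were called by limma in growing cells, where 117 had an unadjusted p under 0.05, and 3 were called without growing vector replicate 2. In low serum 3 genes were called, the metallothioneins MT1H and MT2A, which rose by 1.55 ± 0.24 (adjusted p = 0.00867) and 1.31 ± 0.18 (adjusted p = 0.0044), and the protease inhibitor TFPI2, which fell by 1.71 ± 0.30 (adjusted p = 0.0407). All 3 were lost without low-serum vector replicate 1 (adjusted p = 0.0814, 0.0662 and 0.2) or low-serum shp107 replicate 2 (adjusted p = 0.6, 0.44 and 1). The count was 5 and 11 without low-serum vector replicates 1 and 2. In confluent cells 1148 genes changed with shp107, 623 higher and 525 lower, and 702 and 641 without confluent shp107 replicates 1 and 2. TNFSF4 rose by 5.62 ± 0.31 (adjusted p = 3.3e-11). IL13RA2 fell by 8.98 ± 0.54 (adjusted p = 1.32e-10), MMP3 by 8.62 ± 0.64 and CXCL3 by 7.32 ± 0.38. With only the confluent vector and shp107 arrays, limma called 129 genes.

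Of 19 inflammatory genes, 16 fell with shp107 at confluence and 0 rose, also when adjusted over the list alone, with a median of -4.03, which was -2.17 and -6.26 without confluent vector replicates 1 and 2 (fry adjusted p = 7.71e-06, adjusted p = 0.0906 with an estimated correlation). Of 26 genes of the protease list, 12 fell and 1 rose, with a median of -0.95 and 14 lower when adjusted over the list alone (fry adjusted p = 3.16e-08, camera adjusted p = 0.0249). Of 18 contractile genes, 9 rose and 0 fell, with a median of 0.73 and 13 higher when adjusted over the list alone (fry adjusted p = 2.38e-06, adjusted p = 0.0616 with an estimated correlation). Of 29 matrix genes, 11 rose and 2 fell, with a median of 0.78, or 0.32 without confluent vector replicate 1 (fry adjusted p = 0.00216, adjusted p = 0.298 with an estimated correlation). Of 16 immediate early genes, 8 fell and 1 rose, with a median of -0.98 (fry adjusted p = 1.57e-06, adjusted p = 0.0557 with an estimated correlation). NR4A2 fell by 7.25 ± 0.41.

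The confluent shRB and shp107 effects correlated over 8511 genes with r = 0.913 (0.503 from shared arrays in simulation with no true change), and 0.819 without shared arrays. Of the called genes, 427 were higher with both hairpins (43.6 if independent), 457 lower with both (54.9) and 0 opposite. By limma in confluent cells, shRB and shp107 differed in 2 genes, shRB and shp130 in 1591, and shp107 and shp130 in 1412. In senescent cells the shRB and shp107 effects had r = 0.222, against 0.499 from shared arrays alone, and r = 0.0463 without shared arrays.

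In senescent cells 667 genes changed with shp107, 233 higher and 434 lower, where the median change of all genes was 0.11. The count depended on single arrays, and the 2 shp107 arrays differed with an SD of 0.659 over the genes tested. Replicate 1 was closest to senescent vector replicate 1 of experiment 2 (r = 0.979), ahead of its own replicate (r = 0.960). RBL1 was not called (-0.13), so a loss of p107 was not shown. RGS5 rose by 3.37 ± 0.39 (n = 2 per group, adjusted p = 1.94e-05) and ESM1 by 2.00 ± 0.24. The receptor cofactor LY96 fell by 3.15 ± 0.38 (adjusted p = 2.48e-05) and NR4A2 fell by 2.73 ± 0.41. The protease list (0.22, fry adjusted p = 0.0329, adjusted p = 0.659 with an estimated correlation) lost its call with any 1 array left out. The matrix list (0.35, fry adjusted p = 0.0274, adjusted p = 0.471 with an estimated correlation) lost it without senescent vector replicates 1 and 2 and senescent shp107 replicate 2 (0.23). The DNA replication (-0.05), mitosis (-0.12) and interferon (0.13) lists did not pass.

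With shp130, 5 genes changed in growing cells, with 379 at an unadjusted p under 0.05. EREG rose by 3.30 ± 0.24 (adjusted p = 6.88e-08), from 4.30 ± 0.22 to 7.60 ± 0.05, and RBL2 fell as given above. The count was 10 and 2 without growing vector replicates 1 and 2 and 2 and 3 without growing shp130 replicates 1 and 2. In low serum 23 genes changed with shp130, 20 higher and 3 lower, and 10 higher and 3 lower with arrays shifted to one median. The count was 41 and 5 without low-serum vector replicates 1 and 2 and 6 and 1 without low-serum shp130 replicates 1 and 2.

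In confluent cells 2 genes changed with shp130, RBL2 and the zinc finger gene ZNF331, which fell by 1.12 ± 0.19 (adjusted p = 0.0345) and lost its call without confluent vector replicate 2 or confluent shp130 replicate 1 (adjusted p = 0.0916 and 0.186), against 2 higher and 2 lower after quantile normalization. The count was 223 and 45 without confluent vector replicates 1 and 2 and 11 without confluent shp130 replicate 2. The inflammatory list had a median of 0.49 and did not pass (fry adjusted p = 0.605), while it was 1.30 without confluent vector replicate 1 and -0.58 without confluent vector replicate 2. In senescent cells 142 genes changed with shp130, 66 higher and 76 lower. The count was 71 and 46 without senescent vector replicates 1 and 2 and 54 and 52 without senescent shp130 replicates 1 and 2. The carboxylesterase CES1 rose by 3.82 ± 0.24 (adjusted p = 3.14e-09), from 4.68 ± 0.49 to 8.50 ± 0.17 and the neurofilament gene NEFL by 2.71 ± 0.22 (adjusted p = 2.4e-07). The DNA replication list had a median of 0.16, with 4 genes higher and 8 when adjusted over the list alone (fry adjusted p = 0.376), and it, the mitosis list (0.08) and the inflammatory list (-0.12) did not pass.

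**Figure D4:**
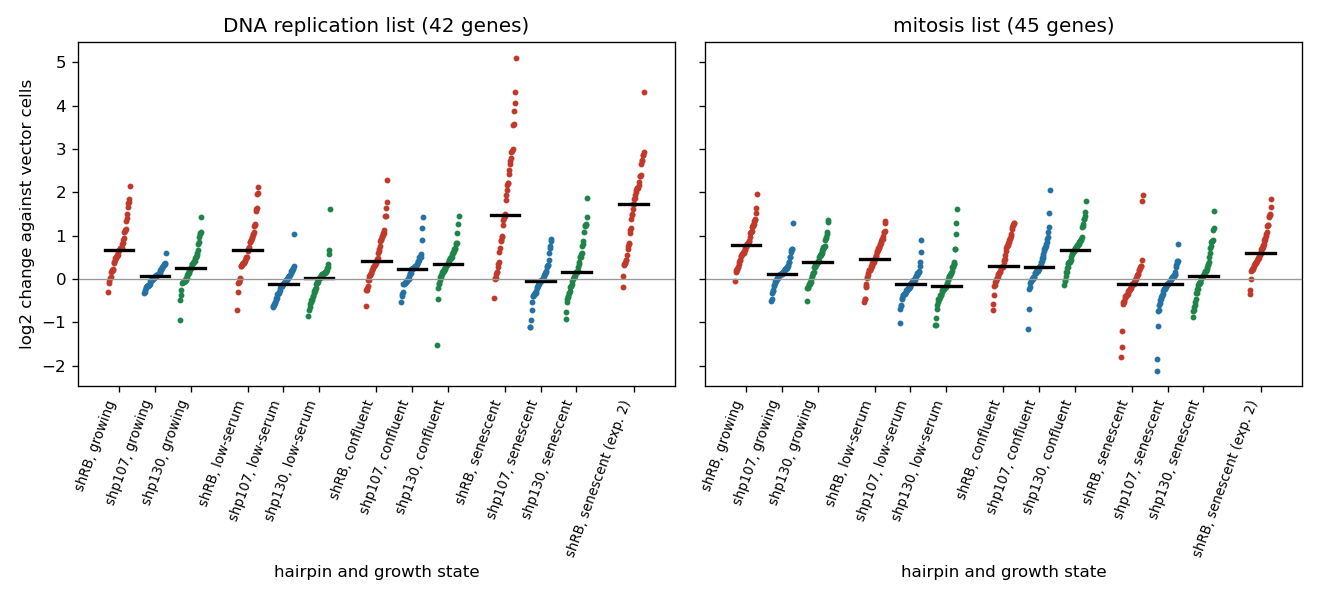
Log2 change against vector (vertical axis) of the members of the DNA replication and mitosis lists with each hairpin in each state (horizontal axis). Points are genes and bars are list medians, and the DNA replication genes lay highest with shRB in senescent cells.

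Differences of the shRB effect between states were tested as interactions. Between senescent and growing cells 169 genes differed, 114 higher and 55 lower in senescent cells. The count was 86, 94, 84 and 92 without growing vector replicate 1, growing shRB replicates 1 and 2 and senescent vector replicate 2. SERPINB4 differed by 5.09 ± 0.68 (adjusted p = 0.000128), PPBP by 4.89 ± 0.57 (adjusted p = 2.43e-05), TYMS by 3.68 ± 0.46 (adjusted p = 4.99e-05) and MCM6 by 2.77 ± 0.37. In the DNA replication list, 11 of 42 genes had a higher shRB effect in senescent cells and 0 a lower one, with a median difference of 0.65 and 19 higher when adjusted over the list alone (fry adjusted p = 0.00768, adjusted p = 0.153 with an estimated correlation), which was 0.46 (adjusted p = 0.0534) without senescent shRB replicate 1. The interferon list differed by 1.497 with 2 genes higher (fry adjusted p = 0.00199, camera adjusted p = 0.0493), the protease list by 0.76 with 2 higher (fry adjusted p = 0.000238, camera adjusted p = 0.0443) and the endothelial list by 1.87 (fry adjusted p = 0.000381, adjusted p = 0.0806 with an estimated correlation). The mitosis list differed by -0.94 with 2 genes lower and did not pass (fry adjusted p = 0.143).

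Between senescent and low-serum cells the shRB effect differed in 149 genes, 42 of them lower in senescent cells, and in 78, 85 and 90 without low-serum vector replicate 1, senescent vector replicate 2 and senescent shRB replicate 1. ESM1 differed by 4.31 ± 0.34 (adjusted p = 2.62e-07), CDC7 by 2.86 ± 0.34, NEXN by -2.87 ± 0.29 and the cell cycle gene CKS2 by -2.53 ± 0.33. The DNA replication list differed by 0.83, with 9 genes higher and 15 when adjusted over the list alone (fry adjusted p = 0.00574, adjusted p = 0.153 with an estimated correlation), and by 0.55 without low-serum shRB replicate 1. The interferon list differed by 1.30, or 2.13 without low-serum vector replicate 2, the protease list by 0.50 and the endothelial list by 1.43 (fry adjusted p = 0.002, 0.00323 and 0.00282, adjusted p = 0.06, 0.153 and 0.161 with an estimated correlation).

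Between senescent and confluent cells it differed in 1186 genes, 710 higher and 476 lower in senescent cells, against 658 and 681 after quantile normalization, and in 736 without confluent shRB replicate 1. RGS5 differed by 12.02 ± 0.55 (adjusted p = 2.29e-12), IL13RA2 by 9.44 ± 0.76 and TNFSF4 by -5.13 ± 0.43. The inflammatory list differed by 5.28 with 13 genes higher (fry adjusted p = 4.73e-05, adjusted p = 0.153 with an estimated correlation), or 3.33 without confluent vector replicate 1. The protease list differed by 1.95 (fry adjusted p = 5.44e-08, camera adjusted p = 0.0249) and the contractile list by -1.29 (fry adjusted p = 8.96e-06, camera adjusted p = 0.0493). The DNA replication list differed by 1.11, with 16 genes higher and 20 when adjusted over the list alone (fry adjusted p = 0.002, adjusted p = 0.296 with an estimated correlation), and the interferon list by 1.02 (fry adjusted p = 0.00483, adjusted p = 0.271 with an estimated correlation). The matrix, endothelial and immediate early lists differed by -0.81, 1.68 and 0.84, the last 1.43 without confluent vector replicate 2 (fry adjusted p = 0.00781, 0.000764 and 0.000569, adjusted p = 0.267, 0.354 and 0.343 with an estimated correlation).

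The hairpins were compared with each other in senescent cells. Between shRB and shp107 1923 genes differed, 984 higher and 939 lower with shRB. The count depended on which array was left out. CCNE2 was higher with shRB by 5.82 ± 0.42 (n = 2 per group, adjusted p = 7.19e-09), the PCNA-associated PCLAF by 5.39 ± 0.50 and IL33 by 5.22 ± 0.73, and GAS6 differed by -3.05 ± 0.39 and cyclin D2, CCND2, by -3.54 ± 0.53. In the DNA replication list, 30 of 42 genes were higher and 1 lower with shRB, with a median of 1.82 (fry adjusted p = 1.57e-06, adjusted p = 0.06 with an estimated correlation). The mitosis list had a median of -0.12 and a mean of 0.07 and did not pass (fry adjusted p = 0.934). The interferon list differed by 1.37 with 5 genes higher (fry adjusted p = 0.000389, adjusted p = 0.161 with an estimated correlation), or 0.89 without senescent shRB replicate 1. The contractile list differed by -0.44 with 2 genes higher and 4 lower (fry adjusted p = 0.00504, adjusted p = 0.587 with an estimated correlation) and the endothelial list by 1.30 (fry adjusted p = 0.000338, adjusted p = 0.299 with an estimated correlation).

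Smaller list differences between shRB and shp107 were lost without senescent shp107 replicate 2. These were the matrix (-0.23), E2F family (-0.36) and lysosome (-0.34) lists (fry adjusted p = 0.0391, 0.0223 and 0.022, adjusted p = 0.724, 0.836 and 0.693 with an estimated correlation). Without that array they gave -0.11, -0.19 and -0.33. The matrix call was also lost without senescent shRB replicate 1, and its median was -0.35 without senescent shp107 replicate 1. The E2F family and lysosome calls were also lost without senescent shRB replicate 2 (-0.06 and -0.33). The E2F family list holds RB1, and without RB1, RBL1 and RBL2 it was not called (-0.39, adjusted p = 0.700).

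Between shRB and shp130 1070 genes differed, 670 higher and 400 lower with shRB, and 537, 534 and 555 without senescent shRB replicate 1 and senescent shp130 replicates 1 and 2. CCNE2 was higher with shRB by 6.03 ± 0.42 (adjusted p = 3.28e-09), SERPINB4 by 5.94 ± 0.48 and RBL2 by 3.14 ± 0.26, and CES1 differed by -4.76 ± 0.24 (adjusted p = 4.28e-11) and NEFL by -4.23 ± 0.22. Among the 42 DNA replication genes, 24 were higher and 2 lower with shRB, with a median of 1.35 (fry adjusted p = 8.96e-06, adjusted p = 0.0906 with an estimated correlation). The mitosis list had a median of -0.15 and did not pass (fry adjusted p = 0.632). The interferon list differed by 1.69 with 5 genes higher (fry adjusted p = 0.000138, adjusted p = 0.0806 with an estimated correlation) and the endothelial list by 1.42 (fry adjusted p = 0.000238, adjusted p = 0.233 with an estimated correlation). The protease list differed by 0.13 (fry adjusted p = 0.0077, adjusted p = 0.366 with an estimated correlation), lost its call without replicate 1 of shRB (adjusted p = 0.0741) or of shp130 (0.05, adjusted p = 0.0923), and was 0.25 and 0.28 without their replicates 2.

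Experiment 2 repeated senescence and shRB on 6 further arrays. There 3339 genes changed with senescence, 1588 higher and 1751 lower, and 1822 and 1854 without senescent vector replicates 1 and 2. The cytokine IL1B rose by 8.56 ± 0.25 (n = 2 per group, adjusted p = 2.76e-07), CCL20 by 8.44 ± 0.18 (adjusted p = 1.1e-07), TNFSF15 by 8.32 ± 0.20 and IL1A by 7.63 ± 0.20, and COL15A1 fell by 5.90 ± 0.19. Of 45 mitosis genes, 44 fell and 0 rose, also when adjusted over the list alone, with a median of -3.69 (fry adjusted p = 8.77e-05, camera adjusted p = 0.0289). Of 42 DNA replication genes, 37 fell and 1 rose, with a median of -1.97 (fry adjusted p = 9.81e-05, camera adjusted p = 0.0289). Of 19 inflammatory genes, 15 rose and 0 fell, with a median of 5.02 (fry adjusted p = 0.000242, adjusted p = 0.122 with an estimated correlation). Of 29 matrix genes, 23 fell and 0 rose, with a median of -1.35 (fry adjusted p = 0.00152, adjusted p = 0.157 with an estimated correlation). Of 18 contractile genes, 12 fell and 1 rose, with a median of -0.77 (fry adjusted p = 0.00066, adjusted p = 0.122 with an estimated correlation). In the protease list 15 genes rose and 6 fell. Its median was 1.04 (fry adjusted p = 0.000136, adjusted p = 0.122 with an estimated correlation).

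Of 20 p53 targets, 6 rose with senescence in experiment 2 and 0 fell (0.35, fry adjusted p = 0.00127, adjusted p = 0.157 with an estimated correlation), and of 17 cholesterol genes, 9 rose and 1 fell (0.71, fry adjusted p = 0.00428, adjusted p = 0.208 with an estimated correlation), lost without senescent vector replicate 1 (adjusted p = 0.0509). The calls of 4 lists were lost without senescent vector replicate 1 or 2. These were the cell cycle inhibitors (1.19, fry adjusted p = 0.0189, then 0.123 and 0.104), the RAS and ERK genes (0.69, 0.00526, then 0.0611 and 0.0592), the lysosome genes (0.27, 0.00872, then 0.0769 and 0.0657) and the immediate early genes (0.24, 0.0143, then 0.0793 and 0.104). In this order they had adjusted p = 0.617, 0.247, 0.208 and 0.43 with an estimated correlation. The lysosome median was 0.58 without growing vector replicate 1 and the immediate early median 0.06 without senescent vector replicate 2. Without x_at and s_at probe sets the immediate early list reversed its tested direction (0.28, adjusted p = 0.991). CDKN2B rose by 3.86 ± 0.24, CDKN1A by 1.92 ± 0.16, CDKN2A by 1.19 ± 0.22 and DUSP4 by 5.51 ± 0.23, and CDKN1B fell by 2.20 ± 0.22. The E2F family (-0.38) and endothelial (-0.51) lists did not pass.

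With shRB 1710 genes changed in senescent cells of experiment 2, 924 higher and 786 lower, and 351 and 289 without senescent vector replicates 1 and 2 and 831 without senescent shRB replicate 2. CCNE2 rose by 4.32 ± 0.18 (n = 2 per group, adjusted p = 4.35e-05), PCLAF by 3.33 ± 0.18 and the licensing factor CDC6 by 2.92 ± 0.17 (adjusted p = 0.00015). CCND2 fell by 2.46 ± 0.22 (adjusted p = 0.000427) and CES1 by 2.21 ± 0.18. Of 42 DNA replication genes, 33 rose and 0 fell, with a median of 1.73 and 35 higher when adjusted over the list alone (fry adjusted p = 9.81e-05, camera adjusted p = 0.0289). Of 45 mitosis genes, 23 rose, 0 fell and 22 were not called, with a median of 0.61 and 25 higher when adjusted over the list alone (fry adjusted p = 0.00127, adjusted p = 0.088 with an estimated correlation). The spindle gene NUSAP1 rose by 1.86 ± 0.16 and the kinase gene CDK1 by 1.66 ± 0.22. The protease list rose by 0.26 with 6 genes higher (fry adjusted p = 0.00607, adjusted p = 0.144 with an estimated correlation), lost without senescent vector replicates 1 and 2 (adjusted p = 0.0611 and 0.0657), and of 5 cell cycle inhibitors 0 were called by limma (0.07).

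The inflammatory list rose with shRB in experiment 2 by 0.90 with 11 genes higher (fry adjusted p = 0.0122, adjusted p = 0.203 with an estimated correlation) and the interferon list by 0.65 with 4 higher and 1 lower (fry adjusted p = 0.0143, adjusted p = 0.218 with an estimated correlation). IFI6 rose by 2.27 ± 0.32 and IFIT1, a gene for an RNA-binding protein, by 2.00 ± 0.16. Both calls were lost with any 1 array left out. The adjusted p of the inflammatory list was 0.0793 and 0.09 without senescent vector replicates 1 and 2 and 0.065 and 0.0652 without senescent shRB replicates 1 and 2, and that of the interferon list 0.117, 0.104, 0.0884 and 0.0652. The endothelial list rose by 1.32 (fry adjusted p = 0.00607, adjusted p = 0.223 with an estimated correlation), lost without senescent vector replicates 1 and 2 (adjusted p = 0.0628 and 0.0657).

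Between the experiments, 611 genes were higher with senescence in both (146 if independent), 980 lower in both (284) and 9 opposite. Of the 2166 genes called in experiment 1, 95.1% had the same sign in experiment 2, and the changes of all genes correlated with r = 0.824. With shRB in senescent cells, 267 genes were higher in both experiments (55.3 if independent) and 11 were opposite, 84.3% of 830 had the same sign, and r was 0.528. Of the 1382 genes called lower with senescence in experiment 1, 24.2% rose with shRB in experiment 2 and 6.08% fell (median 0.18). Rises were 8.48% of 6345 not called (odds ratio 3.44) and 6.63% of 784 called higher. With the experiments swapped, 12.2% of 1751 rose (median 0.10). Rises were 3.58% of 5172 not called (odds ratio 3.75) and 6.93% of 1588 called higher, so that ratio is not from the fall alone. Of 26 DNA replication genes that fell in experiment 1, 22 rose with shRB in experiment 2, with medians of -1.96 and 1.89. Of 40 mitosis genes that fell, 21 rose, with medians of -3.27 and 0.65, while their median shRB effect in experiment 1 was -0.12.

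**Figure D5:**
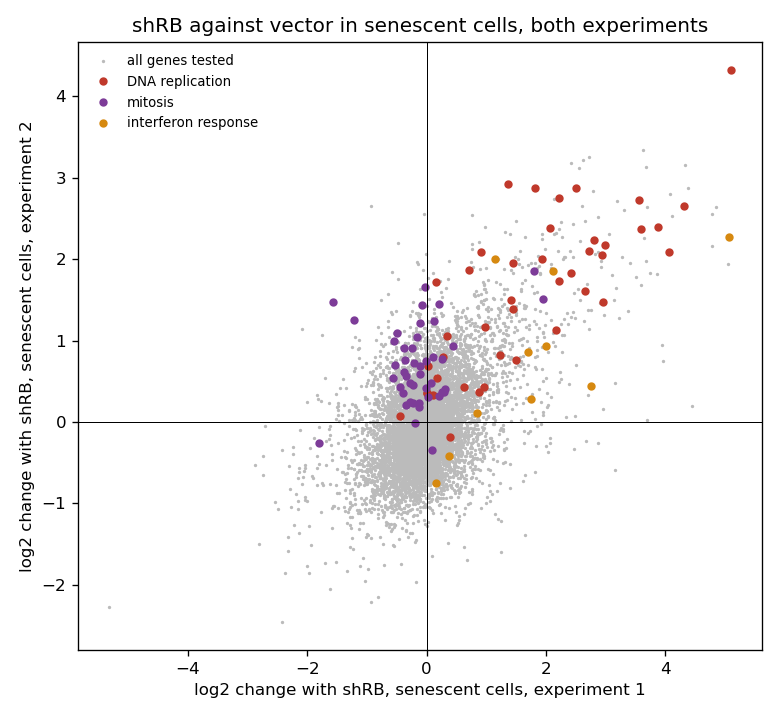
Log2 change with shRB in senescent cells in experiment 1 (horizontal axis) and experiment 2 (vertical axis), n = 2 arrays per group. Each point is a gene, with DNA replication genes in red, mitosis genes in purple, interferon response genes in orange and others in grey. The mitosis medians were -0.12 on the horizontal and 0.61 on the vertical axis.

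Groups of 2 arrays leave single arrays to decide many of the calls given above, and the replicates of confluent vector and senescent shp107 cells differed more than others. With an estimated correlation 14 list calls hold. Cholesterol synthesis holds in low serum, and the protease list with shRB in growing and confluent cells and with shp107 in confluent cells. Contractile genes hold with shRB in confluent cells, and DNA replication and interferon genes with shRB in senescent cells. The difference from growing cells holds for the protease list and interferon genes, and that from confluent cells for the protease list and contractile genes. In experiment 2 DNA replication and mitosis hold with senescence, and DNA replication with shRB.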

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

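In this part, the tests of the confluent inflammatory pattern, of the RB1 knockdown in the mitosis pattern and of every state, any hairpin and the hypothesis in the interferon pattern were chosen only after the result was seen. Each result listed next stood out because the shRB effect differed between senescent cells and another state by a test of the difference itself. By limma, 169 genes differed from growing, 149 from low-serum and 1186 from confluent cells. Against growing cells the lists for DNA replication (0.65), proteases (0.76), interferon response (1.497) and endothelial markers (1.87) differed, those for DNA replication and endothelial markers with adjusted p = 0.153 and 0.0806 with an estimated correlation. DNA replication also lost its call without senescent shRB replicate 1 (0.46, adjusted p = 0.0534). Genes that differed were IL33 (5.21), SERPINB4 (5.09), PPBP (4.89), IFI6 (4.87), RGS5 (4.74), MAP3K7CL (-3.21), FAM171B (-2.95), DDIT4L (-2.95), RBMS3 (-2.95) and GLT8D2 (-2.92). Of these, IL33, IFI6, MAP3K7CL, FAM171B and GLT8D2 lost their calls without senescent vector replicate 2, IL33, IFI6 and FAM171B without senescent shRB replicate 1 (with IFI6 at 2.97), and MAP3K7CL without senescent shRB replicate 2. IFI6, MAP3K7CL and FAM171B lost them without growing vector replicate 1, IFI6 and MAP3K7CL without growing shRB replicate 1, IFI6 and FAM171B without growing shRB replicate 2, and IFI6 without growing vector replicate 2 and senescent vector replicate 1. Against low-serum cells the same 4 lists differed by 0.83, 0.50, 1.30 and 1.43, with all calls lost (adjusted p = 0.153, 0.153, 0.06 and 0.161 with an estimated correlation). Genes that differed were SERPINB4 (4.84), PPBP (4.71), IFI6 (4.66), RGS5 (4.45), ESM1 (4.31), NEXN (-2.87), FGF5 (-2.71), LINC00622 (-2.62), ALG14 (-2.54) and CKS2 (-2.53), of which IFI6 and ALG14 lost their calls without senescent vector replicate 2 (adjusted p = 0.104 and 0.147), low-serum vector replicate 1 (adjusted p = 0.208 and 0.0854) and low-serum shRB replicate 1 (adjusted p = 0.0694 and 0.0838). IFI6 also lost it without low-serum shRB replicate 2, senescent vector replicate 1 and senescent shRB replicate 1 (adjusted p = 0.0873, 0.0999 and 0.174, the last with 2.76), and ALG14 without low-serum vector replicate 2 and senescent shRB replicate 2 (adjusted p = 0.0634 and 0.108). Against confluent cells the lists for DNA replication (1.11), inflammatory factors (5.28), proteases (1.95), matrix (-0.81), contractile genes (-1.29), interferon response (1.02), immediate early genes (0.84) and endothelial markers (1.68) differed. Only proteases (camera adjusted p = 0.0249) and contractile genes (camera adjusted p = 0.0493) held, and the others, in this order, had adjusted p = 0.296, 0.153, 0.267, 0.271, 0.343 and 0.354 with an estimated correlation. Genes that differed were RGS5 (12.02), IL13RA2 (9.44), MMP3 (8.51), CXCL6 (8.33), CXCL3 (8.17), ATP8B1 (-6.52), GAS6 (-6.05), TNFSF4 (-5.13), MEST (-5.11, or -3.14 without confluent vector replicate 1) and MAP3K7CL (-4.84).

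In confluent cells the inflammatory list was lower with shRB and with shp107 than with vector, and not with shp130, with adjusted p = 0.153 for shRB and adjusted p = 0.0906 for shp107 with an estimated correlation. Against the shp130 arrays the shRB median was -5.43 (fry in limma, p = 1.17e-07, 19 of 19 genes lower), which argues against the vector arrays alone standing apart, and the correlation of 0.819 from contrasts that share no array argues against chance values of the shared vector arrays. For a weaker exit from the cell cycle, shRB cells kept 80.5% of the fall of the mitosis list in vector cells, shp107 cells 84.5% and shp130 cells 76.3%. Single shRB and shp107 arrays ran from 68.1% to 102%, so the bound of 80% did not decide. That bound was applied with the spread of the arrays after its value was seen. The shp130 arrays kept 54.9% and 89.05%, yet their inflammatory means were 10.93 and 10.97. The shRB and shp107 arrays lay between 6.26 and 6.69, which argues against a weaker exit alone as the cause. A difference in handling or harvest between the 2 sets of confluent cultures may explain the pattern, since shRB and shp107 differed from each other in 2 genes. The labels give no batch, so handling and an effect of the 2 hairpins cannot be told apart, and RBL1 was not called with shp107 at confluence (-0.48), so a loss of p107 was not shown.

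The mitosis list rose with shRB in senescent cells of experiment 2 and had a median near 0 in experiment 1. That rise had adjusted p = 0.088 with an estimated correlation. A weaker knockdown in experiment 1 is argued against by RB1, which fell more there, with a difference of -3.04 ± 0.40 (SE from the fit of all probe sets). A single array is argued against by the medians in experiment 1, which ran from -0.26 to -0.0512 with 1 array left out. The difference between experiments was 0.76 over the list and did not pass, with 0.0663 from fry in limma against a limit of 0.05, so spread between arrays without a difference between the experiments may explain the pattern and stays open.

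The interferon list, whose filter could favour this, rose with shRB in senescent cells of experiment 1. Its highest median with shRB in the other states was 0.128, and its highest median with shp107 or shp130 in senescent cells was 0.15. How many genes passed the filter only through the senescent shRB arrays was not counted. Such genes would be low in the other groups by selection. These medians therefore do not decide against a response to the construct in every state or to any hairpin. A single array is argued against by the highest adjusted p of 0.00148 with 1 array left out, where medians ran from 1.20 to 2.33. A hypothesis is that loss of RB in senescent cells raised interferon response genes, which stays open. In experiment 2 the median was 0.65 (adjusted p = 0.218 with an estimated correlation) and ran from 0.52 to 0.74 with 1 array left out. The highest adjusted p was then 0.117, which with so few arrays does not tell a smaller rise from a weaker test.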

How the results depend on the processing

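The tests with shp130 arrays as the confluent reference, with a crossed block and with the E2F family list without RB1, RBL1 and RBL2 were chosen only after the result was seen. Unless stated, values are numbers of genes called by limma, and the cause of a change was not tested. Groups of 2 arrays and the low signal of most probe sets over background limit what was called.

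With 1 array left out, counts ran from 439 to 813 for low serum, 909 to 1845 for confluence and 1337 to 1490 for senescence. For shRB they ran from 1 to 29 in growing, 2 to 16 in low-serum, 751 to 1874 in confluent and 376 to 609 in senescent cells, for shp107 from 0 to 3, 0 to 11, 641 to 1513 and 183 to 1477, and for shp130 from 2 to 10, 1 to 41, 3 to 223 and 46 to 71 in the same order. Differences of the shRB effect in senescent cells ran from 84 to 145 against growing, 78 to 165 against low-serum and 736 to 1584 against confluent cells. In senescent cells shRB against shp107 gave 567 to 2556 and against shp130 534 to 860. In experiment 2 senescence gave 1822 to 3441 and shRB 289 to 1227. The median shRB effect on genes that fell in senescence ran from 0.16 to 0.21, was 0.23 after quantile normalization and 0.097 with the experiments swapped.

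With only the arrays of the groups compared, so with fewer arrays, low serum gave 656 and confluence 352. Not every count fell, since senescence gave 2321 against 2166, and in experiment 2 shRB gave 2440 against 1710. The shRB counts in growing, low-serum, confluent and senescent cells were 3, 0, 75 and 300, the shp107 counts in the last 3 states 0, 129 and 0, and the shp130 counts 3, 0, 0 and 14. Where limma gave 0, all arrays together had 704, 354, 1850, 471 and 456 genes at an unadjusted p under 0.05. Differences of the shRB effect gave 1.1e+02, 29 and 304, shRB against shp107 87 and against shp130 521.

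Without x_at and s_at probe sets, which leaves fewer genes, low serum gave 727, shRB 2 in growing and 4 in low-serum cells, shp107 1 in low-serum and 314 in senescent cells, shp130 5 in low-serum cells, differences of the shRB effect 98 against growing and 96 against low-serum cells and shRB against shp107 1180. The immediate early list in senescence of experiment 2, with a median of 0.24, reversed its tested direction, with a median of 0.28. With the mean of all probe sets, shRB gave 11 and shp107 7 in low-serum and shp130 1 in confluent cells. In one fit of 38 arrays shRB gave 53 in growing, 11 in low-serum and 694 in senescent cells of experiment 2, and shp130 8 in growing and 4 in confluent cells. A variance prior with trend and robust weights gave 22 for shp107 and 51 for shp130 in low-serum and 1 for shp130 in confluent cells. Quantile normalization gave 32 for shRB in growing cells and 8 and 4 for shp130 in growing and confluent cells, and a shift to one median 3 for shRB in low-serum cells and 3 and 13 for shp130 in growing and low-serum cells.

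With the replicate number as a block over all states, shRB gave 29 in growing cells and 2637 in experiment 2, and shp130 1 in confluent cells. As a block within each state, shRB gave 40 in growing cells and 2649 in experiment 2, shp107 5 in low-serum cells and shp130 3 in growing cells. The correlation of replicate differences ran from -0.21 to 0.49, and in the 7 comparisons where it was negative a crossed block gave 4 for shp130 in confluent cells and left the other counts within 1.5 times. With the shp130 arrays as the confluent reference, shRB gave 1591 and shp107 1412. Without the filter on dim genes all counts stayed within 1.5 times.

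Of 522 calls of named genes, 369 were kept and 153 lost with only the arrays compared, where 3 of 128 uncalled values were called, and 518 were kept and 4 lost with quantile normalization. With 1 array left out, of 2360 values of called genes 2042 kept the call and 318 lost it, and 8 of 680 others gained one. Of 89 list calls, 14 were kept and 75 lost with an estimated correlation, 18 kept and 71 lost with only the arrays compared, and 71 kept and 18 lost with the block within each state, where 5 of 241 others gained one. Without RB1, RBL1 and RBL2, 0 of 2 calls of the E2F family list were kept. With 1 array left out, of 420 values of called lists 365 kept the call and 55 lost it, and 31 of 1080 others gained one.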

Other observations

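No test was added for this part. In low serum the transcription factor gene TOX rose by 4.67 ± 0.67 (SE, n = 2 per group), the protease ADAMTS8 by 4.39 ± 0.69 and the cytokine TSLP by 4.29 ± 0.63. In senescent cells of experiment 2 the matrilin MATN2 fell by 5.02 ± 0.27 and the chemokine CXCL12 fell by 5.02 ± 0.22. Of 38 arrays, 23 were closest in correlation to their own replicate, the confluent vector arrays were each closest to a confluent shp130 array and senescent shp107 replicate 1 to an experiment 2 array.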
